A study of Mus musculus with 4 samples.

How the data were processed

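The series holds 2 droplet libraries (10x Genomics 3' chemistry) of sorted CD45-positive, MHC class I-positive cells from BeCon tumour-bearing B6 mice, one of ascites and the other of spleen and blood. The files give UMI counts per gene and per hashtag antibody for each barcode, deposited as matrices that Cell Ranger 6.1.1 made on the mm10 genome, per the file headers. The treatment, mouse number and tissue of each hashtag come from the deposited hashtag notes. Ascites has 4 vehicle and 4 treated mice, and spleen and blood have 3 of each (vehicle mice 1 to 3, treated mice 2 to 4).

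Barcodes with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept, 11112 of 13688 in ascites and 11512 of 14792 in spleen and blood. Hashtags were assigned with HTODemux of Seurat 5.3.0 (positive quantile 0.99). It called 37.9% and 35.7% of these barcodes doublets and 22.8% and 16.4% negative, which left 4368 and 5514 cells. Of the called doublets, 2354 and 1813 had a top hashtag with at least 80% of at least 20 hashtag UMIs. These had medians of 12183.5 and 6081 UMIs, against 5575 and 5614.5 in the kept cells. Cells with much RNA were therefore lost more often, most of all in ascites. Scrublet called 0 doublets in both libraries, so it removed nothing.

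Each library was normalized to 10000 UMIs per cell and clustered in scanpy 1.11.5 with Leiden (leidenalg 0.10.2, resolution 1) on 20 neighbours in 30 principal components of 2000 variable genes. Clusters were named from marker lists, as macrophage-like, B cell-like and so on, and the suffix is left out below. Clusters that met no rule are given by number with their lineage, or left unnamed. Unnamed clusters held 12.9% and 15.5% of vehicle and treated ascites cells, 11.7% and 8.70% of spleen cells and 12.3% and 13.0% of blood cells.

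Shares of kept cells were compared between mice with an exact two-sided permutation test of the difference of means, with Benjamini-Hochberg (BH) adjustment over the classes of a tissue. For expression, counts were summed per mouse and class. A mouse entered with at least 20 cells, and a class was tested where each arm had at least 2 such mice. Genes were tested with edgeR 4.0.16 (two-sided robust quasi-likelihood F test, TMM, filterByExpr) in R 4.3.3, with BH adjustment and a threshold of 0.05. Fixed gene lists were tested two-sided with camera of limma 3.58.1 on voom values (inter-gene correlation 0.01), with an estimated correlation and fry beside it and BH adjustment over the lists of a class. The difference between tissues was an edgeR interaction term with the mouse as a block, taking equal numbers in the hashtag notes as the same animal. On simulated counts with known changes, edgeR recovered 43.9% of 2-fold and 95.3% of 4-fold changes at the size of ascites CD4 T cells, 19.5% and 88.6% for ascites CD8 T cells, and 75.8% and 100% for ascites macrophages. For CD8 T cells of spleen and blood it recovered 69.0% and 64.4% of 2-fold changes. The simulated counts followed the dispersion trend of edgeR, without extra spread of single genes, so recovery in the real data may be lower.

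These tests, the gene lists and the rule for named genes were chosen before the data were examined. The rule takes, for CD4 and CD8 T cells and ascites macrophages, the 10 largest changes in each direction among genes past the threshold with a mean logCPM of at least 4 and no overlap between arms. It adds up to 4 members per fixed list past the threshold, and always Sik1, Sik2, Sik3, Nr4a1, Crem, Il10, Foxp3, Pdcd1, Gzmb, Ifng and Tcf7 where tested. In other classes it takes the 3 genes with the smallest p in each direction, and where none passes the 5 with the smallest p. Some genes that the rule takes are not reported here. A gene outside this rule, such as Crem in cDC1 and monocytes or the shared genes, was chosen after its values were seen. Leading genes of a cluster are not given as results of that cluster's own class, with few exceptions. These are Tcf7 in CD4 and CD8 T cells, Ifng in ascites CD8 T cells and Ffar2 in cDC2.

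The alternatives fixed beforehand were a stricter hashtag rule, keeping Scrublet doublets, at most 5% mitochondrial UMIs, a transcript gate for T cells, leaving out each mouse, at least 10 or 50 cells per mouse, no low-count filter, DESeq2 size factors, the DESeq2 1.42.0 Wald test, a replicate block, log odds, and the share of lymphocytes. Added after seeing the data were the hashtag fraction rule alone (80% of at least 20 hashtag UMIs), leaving out the 5% of cells with the highest Scrublet scores, edgeR on cell counts, leaving out unnamed clusters or both mice numbered 4, summed transcripts, all macrophage clusters together, and each cluster of the B and CD8 T cell classes alone.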

Results

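Single-cell RNA sequencing measured the immune cells of B6 mice that carried the BeCon tumour, named in the series title as a model of ovarian cancer, after treatment with YKL-05-099 or its vehicle. YKL-05-099 is a small-molecule inhibitor of the salt-inducible kinases, which hold the CRTC coactivators of the transcription factor CREB out of the nucleus. Live cells positive for CD45 and MHC class I were sorted, labelled with a hashtag antibody per mouse and tissue, and pooled into 2 droplet libraries. The ascites library held 4 vehicle and 4 treated mice. The other library held spleen and blood of 3 vehicle mice and 3 treated mice. Its total was 92064806 UMIs (unique molecular identifiers, counted transcripts) over 14792 barcodes, and that of ascites was 134034611 UMIs over 13688 barcodes. After filtering and assignment to a mouse, 4368 ascites cells and 5514 spleen and blood cells remained, with medians of 5575 and 5614.5 UMIs per cell. Per mouse these were 289 to 873 ascites cells, with 2284275 to 7758416 UMIs. Spleens gave 485 to 649 cells per mouse and blood samples 302 to 426. The mouse was the replicate in every test. Cell classes are clusters named by marker transcripts, so that "macrophage" below means a macrophage-like cluster.

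The first question was whether the kinase inhibitor altered the makeup of the immune cells in ascites. Treated ascites held fewer B cells and NK cells and more cells of a T cell cluster marked by Rora, Gata3 and Ikzf2 (cluster 11) and more migratory dendritic cells. B cells made up 27.0% ± 7.17 of the kept cells in vehicle mice and 16.4% ± 3.09 in treated mice (mean ± SD, n = 4 each). NK cells were 2.69% ± 1.5 and 0.866% ± 0.319. Cluster 11 went the other way, from 2.08% ± 0.443 to 7.95% ± 3.24, and so did the migratory dendritic cells, marked here by Fscn1 and Ccl22, from 2.62% ± 0.941 to 7.76% ± 2.85. For these 4 classes every treated mouse lay on one side of every vehicle mouse. Each had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 mice allow, and an adjusted p of 0.0667 over the classes of ascites, so none passed the correction.

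Of the leading genes of cluster 11, 5 were measurable in CD4 T cells and 8 in CD8 T cells, and 0 of them differed between the arms there. With 2 mice per arm, only 11 of 3725 genes passed in these CD4 T cells and 0 of 3418 in CD8 T cells. A count of 0 was therefore likely in any case, so this check says nothing about the share of cluster 11. Of those of the migratory dendritic cells, 3 were measurable in cDC2 and 0 differed, while 1 of 2 was lower in treated cDC1. Of the 10 leading genes of the larger B cell cluster, 1 was higher and 1 lower in treated B cells, and of 9 measurable genes of the smaller one 4 were lower.

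**Figure D1:**
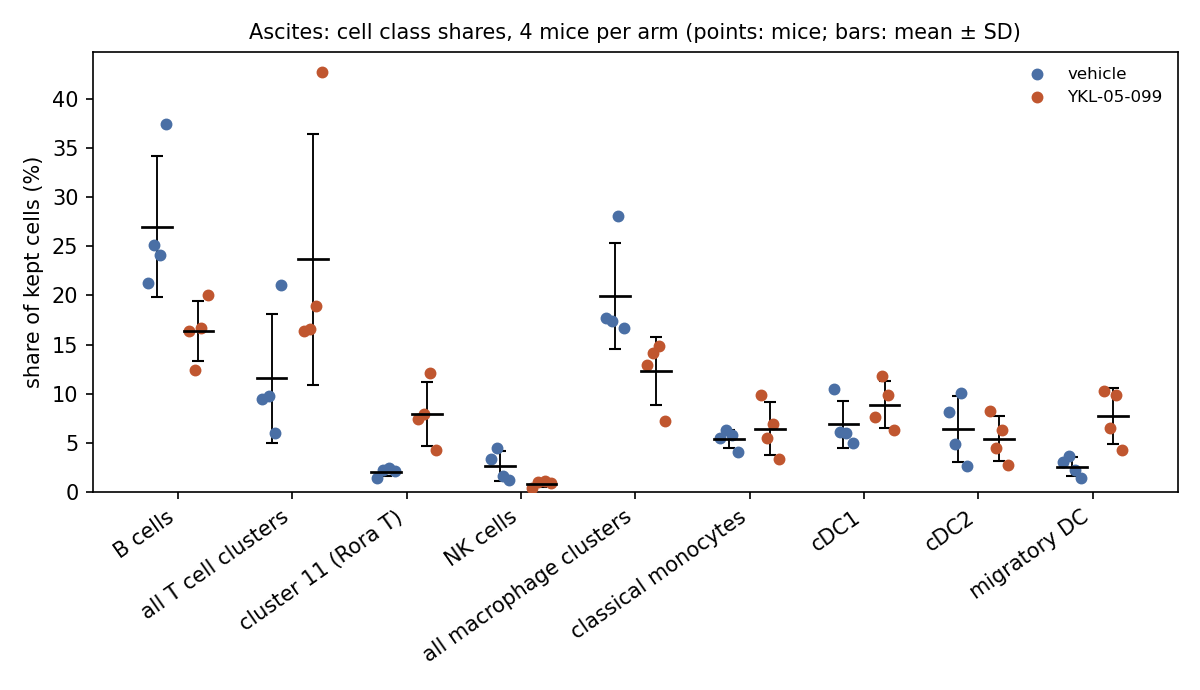
Share of kept ascites cells (%, y axis) in each cell class (x axis) for vehicle and YKL-05-099 mice; each point is a mouse and the bars give the mean ± SD of 4 mice per arm. Cluster 11 lies at 4.30% to 12.2% in treated mice and at 1.45% to 2.47% in vehicle mice.

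T cells as a whole were 11.6% ± 6.57 of vehicle and 23.7% ± 12.7 of treated ascites cells, and the arms overlapped (exact permutation p = 0.114, n = 4 each). Among lymphocytes alone the same difference was 29.1 percentage points, and there every treated mouse lay above every vehicle mouse (exact permutation p = 0.0286, unadjusted, n = 4 each). CD4 T cells were 5.26% ± 4.26 and 9.11% ± 9.97, and CD8 T cells 4.23% ± 2.50 and 6.60% ± 5.21, with exact permutation p = 0.514 and p = 0.629 (n = 4 each). Without treated mouse 4, whose CD4 T cells were 24% of its cells, the differences of the means became -1.11 and -0.227 percentage points. Classical monocytes (5.41% ± 0.924 and 6.45% ± 2.71), cDC1 (6.89% ± 2.42 and 8.91% ± 2.40) and cDC2 (6.45% ± 3.34 and 5.46% ± 2.33) overlapped between the arms.

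The macrophage clusters together fell from 19.97% ± 5.39 of vehicle ascites cells to 12.3% ± 3.46 of treated ones, again with every treated mouse below every vehicle mouse (exact permutation p = 0.0286, unadjusted, n = 4 each). The arms filled different macrophage clusters. In treated mice 83.6% of these cells belonged to cluster 1, led by Lgals1, Ltc4s and Gpnmb. In vehicle mice 2.72% did, while 37.9% belonged to cluster 5 (Lyve1, Marco, Cd163), 42.5% to cluster 3 (Cx3cr1, Fcrls, Ms4a7) and 16.9% to cluster 15 (Prg4, Alox15, Cxcl13). Of the measurable leading genes of clusters 1, 5 and 15, 7 of 10, 7 of 10 and 5 of 7 also differed between the arms inside the macrophage class, so the sizes of these clusters were not compared. Of the leading genes of cluster 3, 8 were measurable in macrophages, of which 1 was higher and 2 lower. The macrophage class joins clusters 1 and 5 only, and each arm drew nearly all its cells from 1 of them. Leading genes of clusters 1 and 5 were thus likely to differ there in any case. For cluster 3 the check cannot show whether its cells moved to another cluster. The share of cluster 3 was 8.83% ± 4.78 of vehicle and 1.88% ± 0.821 of treated cells, without overlap (exact permutation p = 0.0286, adjusted p = 0.0667, n = 4 each). Macrophage transcripts summed over all kept cells were lower too, but they move with the level per cell as well as with the share, and C1qa, C1qc and Csf1r also fell within macrophages (below). C1qa, C1qb and C1qc, the complement components that macrophages make, went from 4220 ± 470 to 1824 ± 287 CPM (counts scaled to the total of the mouse). Csf1r, the receptor for the macrophage growth factor CSF1, went from 283.3 ± 16.4 to 135 ± 17.5 CPM (exact permutation p = 0.0286 for each, n = 4 each). Of 5 transcripts of resident peritoneal macrophages 4 were lower on average, Selp (22.1 ± 21.4 to 1.78 ± 0.891 CPM) and Garnl3 (7.30 ± 5.71 to 1.24 ± 0.537) without overlap (exact permutation p = 0.0286 for each, n = 4 each). Gata6 (9.09 ± 9.0 to 3.1 ± 4.07 CPM) and Icam2 (26.2 ± 20.4 to 14.4 ± 3.17) overlapped (exact permutation p = 0.257 for each), as did Timd4, the one that was higher (20.7 ± 9.40 to 39.7 ± 10.5, exact permutation p = 0.0571). Vehicle mouse 4 raised the vehicle means, with Selp at 54.1, Garnl3 at 15.9, Gata6 at 22.4 and Icam2 at 56.6 CPM against at most 14.1, 4.86, 6.47 and 19.2 in the other vehicle mice. The call on the share of all macrophage clusters was lost under several settings. With hashtags assigned by their fraction of the hashtag UMIs alone, a rule added after the data were seen, the difference was -6.86 percentage points and the arms overlapped (exact permutation p = 0.343, n = 4 each). Leaving out vehicle mouse 3 or treated mouse 4 gave -4.97 and -5.98 percentage points (exact permutation p = 0.0571 for each), and the arms still did not overlap.

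The second question was how gene expression differed between the arms within the cell classes of ascites. Macrophages had the largest count of changed genes among the classes tested in the main setting. With at most 5% mitochondrial UMIs cDC1 had 900 (4 treated mice) and macrophages 657 (2 treated mice). Treated macrophages had more transcripts of interferon-induced genes and fewer of Il10, Csf1r, Mertk and Axl. MHC class II genes rose in the macrophage class, clusters 1 and 5, but did not pass the threshold once clusters 3 and 15 were summed in. H2-Ab1 and Cd74, the MHC class II beta chain and its invariant chain, rose by 1.76 ± 0.12 and 1.46 ± 0.12 on the log2 scale (± SE, n = 4 each, edgeR adjusted p = 7.5e-09 and 6.7e-07). H2-Ab1 went from 468.4 ± 44.6 to 1568 ± 289 CPM of the class. With all macrophage clusters of a mouse summed, a fit added after the data were seen, H2-Ab1 and Cd74 were at 0.49 and 0.40 (edgeR adjusted p = 0.278 and 0.303). Il10, which encodes the anti-inflammatory cytokine interleukin 10, fell by 2.16 ± 0.21 (edgeR adjusted p = 1.2e-06), from 248.8 ± 65.5 to 54.6 ± 12.5 CPM. Crem, a CREB-responsive gene, rose by 3.07 ± 0.28 (edgeR adjusted p = 1.2e-07), from 8.49 ± 3.83 to 72.8 ± 14.3 CPM. In all, 606 of 6400 genes were higher and 629 lower past an adjusted p of 0.05 by edgeR. Of the vehicle cells 181 of 194 came from cluster 5, and of the treated cells 183 of 185 came from cluster 1. A change within cells therefore cannot be told apart from a replacement of one macrophage population by another. A treated macrophage also held fewer UMIs, with a median of 9695 ± 799 against 18421 ± 928 (exact permutation p = 0.0286, n = 4 each).

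Among the lists fixed in advance, the type I interferon genes stood out in macrophages. Of 15 measured members 13 rose and 0 fell, among them Stat2 (log2 change 2.21 ± 0.26), Irf7 (2.0 ± 0.26), Isg15 (1.68 ± 0.24) and Zbp1 (1.36 ± 0.20). Rsad2, an antiviral enzyme, and Oasl1 were among the 10 largest rises that the naming rule took (2.85 ± 0.44 and 2.80 ± 0.56). The list moved up by camera with a preset correlation (adjusted p = 9.7e-11), and its adjusted p was 0.256 with an estimated correlation. Of 21 interferon gamma and antigen presentation genes 12 rose and 0 fell, including H2-Eb1 (1.67 ± 0.22, but 0.26 and not called in the sum of all macrophage clusters) and the immunoproteasome subunit Psmb10 (0.67 ± 0.14). Camera gave an adjusted p of 6.1e-07, and it was 0.256 with an estimated correlation. Adjusted over the list alone, 13 and 14 members rose.

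Among genes of complement and phagocytosis more fell than rose. Of 19 measured, 7 fell and 1 rose, with falls of C1qa (-0.73 ± 0.09), C1qc (-0.66 ± 0.09) and the TAM receptors Mertk (-1.10 ± 0.17) and Axl (-1.31 ± 0.21), which recognise apoptotic cells. Camera gave an adjusted p of 2.0e-06, and it was 0.3 with an estimated correlation. Adjusted over the list alone, 12 fell and 1 rose. Of 17 alternative and regulatory macrophage genes 7 fell and 1 rose, with Mrc1, the mannose receptor, at -0.91 ± 0.14 and the scavenger receptor Msr1 at -0.68 ± 0.14 (camera adjusted p = 0.0077, and adjusted p = 0.387 with an estimated correlation). Of 8 macrophage marker transcripts 5 fell and 0 rose, including Csf1r (-0.95 ± 0.11) and Adgre1, the F4/80 antigen (-0.99 ± 0.16), with camera adjusted p = 1.7e-05 and adjusted p = 0.256 with an estimated correlation.

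**Figure D2:**
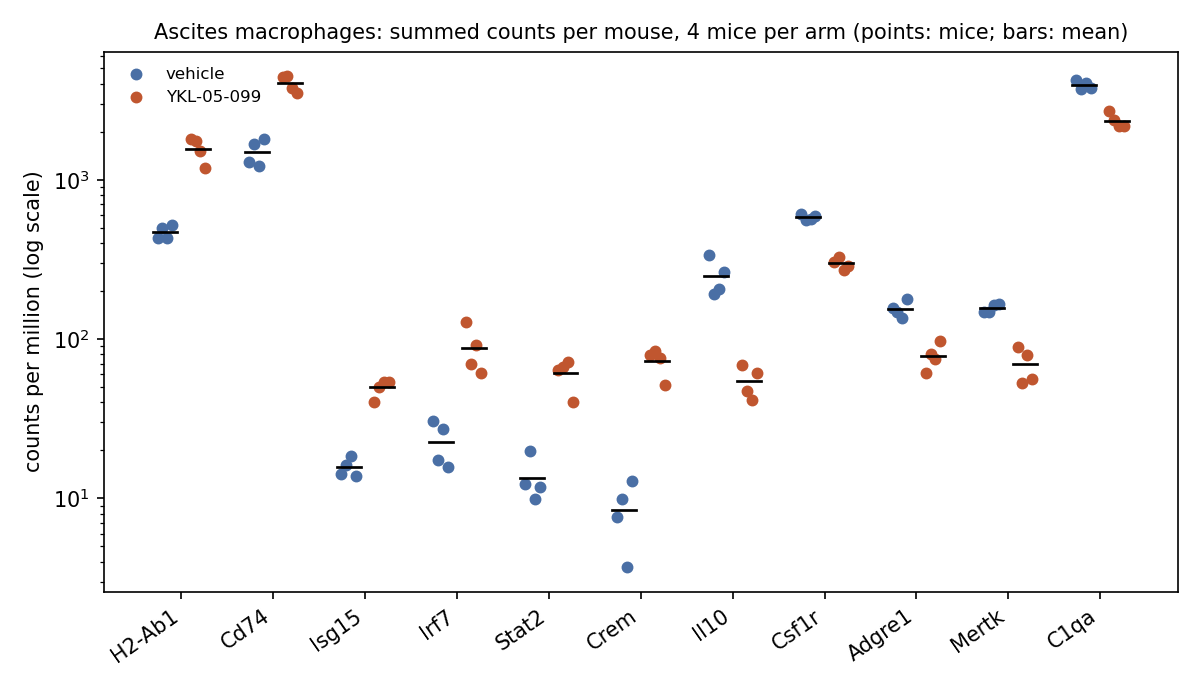
CPM (y axis, log scale) of 11 genes in the summed ascites macrophages of each mouse; points are mice, bars are means of 4 mice per arm. The 6 genes on the left are higher and the 5 on the right lower in every treated mouse than in every vehicle mouse.

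Other named genes of the macrophages were chemokine receptors, heat shock genes and monocyte transcripts. Ccr1 fell by 2.42 ± 0.21, while Cxcr4 rose by 1.45 ± 0.25. Steep falls were seen for Slc7a2 (-5.21 ± 0.88), an arginine transporter, the complement receptor Vsig4 (-5.16 ± 1.19) and Apoc4 (-4.97 ± 0.44). Vsig4 was uneven, at 419.3 CPM in vehicle mouse 1 and 77.53 to 120.1 in the other vehicle mice. It was at 18.01 CPM in treated mouse 4 and at most 2.79 in the other treated mice. Epha2 and Fpr1 were at -4.45 ± 0.45 and -3.87 ± 0.46. The largest named rise was Ly6c2, the Ly6C antigen of classical monocytes (4.98 ± 0.51), from 1.03 ± 0.786 to 37.2 ± 16.1 CPM. Pdpn (3.75 ± 0.52) and Vcan (3.24 ± 0.75) followed. Not all monocyte transcripts rose. Chil3 (0.31), Ccr2 (0.41) and Fn1 (-1.57) did not pass the threshold (edgeR adjusted p = 0.845, 0.294 and 0.0614). F13a1 fell (-1.23, edgeR adjusted p = 0.00042). Of 16 heat shock and unfolded protein genes 7 rose and 1 fell, with Hspe1 at 0.90 ± 0.15 and Hspa8 at 0.64 ± 0.13 (camera adjusted p = 1.7e-05, and adjusted p = 0.387 with an estimated correlation). Il1b, the inflammatory cytokine, rose by 1.62 ± 0.23. Of 15 CREB-CRTC targets 4 rose and 2 fell, with Crem and Nr4a2 (2.20 ± 0.27) among the rises and Il10 and Dusp1 (-0.87 ± 0.13) as the falls (camera adjusted p = 0.421, and adjusted p = 0.786 with an estimated correlation). Sik1, Sik2 and Sik3 were at 0.57 ± 0.34, 0.63 ± 0.37 and 0.41 ± 0.28, and Nr4a1 at -0.02 ± 0.25, none past the threshold (edgeR adjusted p of 0.262 to 0.963, n = 4 each).

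The count for macrophages was 2383 genes with the fraction rule alone, 657 with at most 5% mitochondrial UMIs and 745 with at least 50 cells per mouse. When all macrophage clusters of a mouse were summed, 1284 genes passed, of which 913 were shared with the class alone. In that sum Il1b, at 0.29, was not past the threshold either (edgeR adjusted p = 0.483), while Il10 (-1.97) and Crem (3.21) were. Of the macrophage genes that the naming rule took, 67 kept direction and side of the threshold in the sum. Another 19 lost the threshold, and only some of these are identified here.

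The remaining myeloid and B cell classes of ascites shared a small core of changes with the macrophages. Crem rose in B cells (2.69 ± 0.23), cDC1 (2.95 ± 0.35), cDC2 (3.44 ± 0.32) and classical monocytes (3.30 ± 0.48). Trim25, an interferon-induced gene, and the chaperone Hspe1 rose in all 5 classes, as did Cyth1 and Isy1. Fkbp5, a glucocorticoid-responsive gene, and Zfp36l2, an RNA-binding protein that shortens mRNA life, fell in all 5. Of 3405 genes tested in all 5 classes, 7 were higher in each and 2 lower in each by edgeR at an adjusted p of 0.05. Independent lists would give 0.000741 and 0.000322 genes. The classes come from the same mice and share their free RNA, so they are not independent tests.

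In treated B cells Stat4 (1.77 ± 0.15) and Vps37b (1.58 ± 0.13) rose beside Crem, while Tbc1d9 (-2.90 ± 0.34), the transcription factor Pou2f2 (-1.13 ± 0.12) and Cd52 (-0.81 ± 0.08) fell. By edgeR 193 genes were higher and 253 lower of 5671 (n = 4 each). The mix of B cells differed, with 107 of 700 vehicle and 6 of 325 treated cells in cluster 13. In cluster 0 alone, a fit added after the data were seen, 296 genes passed. Crem, Stat4, Vps37b, Pou2f2 and Cd52 were among them, but not Tbc1d9 (-2.53, edgeR adjusted p = 0.0926). With at most 5% mitochondrial UMIs 27 genes passed, with DESeq2 284, and without treated mouse 4 the count was 296. In cDC1, the dendritic cells that cross-present antigen to CD8 T cells, Gcnt2 rose by 4.06 ± 0.19, Ramp3 by 4.2 ± 0.29 and Antxr2 by 2.04 ± 0.14. The chemokine receptor Ccr2 fell by 2.60 ± 0.16 there, and Fcrla and Fgl2 were at -2.29 ± 0.19 and -1.26 ± 0.11. By edgeR 418 genes were higher and 456 lower of 5799 (n = 4 each), and 575 passed in DESeq2. Of 8 proliferation genes in cDC1 5 rose (camera adjusted p = 0.00016, and adjusted p = 0.215 with an estimated correlation).

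Ramp3, which encodes a partner of the calcitonin and adrenomedullin receptors, also rose in cDC2 (4.55 ± 0.31), with Got1, a transaminase (2.53 ± 0.19), while Zfp36l2 and H3f3b were at -1.0 ± 0.13 and -0.88 ± 0.12. With 4 vehicle and 2 treated mice, 139 genes were higher and 118 lower in cDC2 by edgeR. The total was 745 with the fraction rule alone and 123 in DESeq2, and 148, 111 and 99 without vehicle mouse 3, treated mouse 1 or treated mouse 3. In classical monocytes (4 vehicle and 3 treated mice) Got1 (2.41 ± 0.25), the antiviral Bst2 (1.94 ± 0.20) and Tmsb10 (1.08 ± 0.12) rose, and F13a1 (-1.20 ± 0.16) and Gsr (-1.15 ± 0.17) fell. Of 12 type I interferon genes 9 rose and 0 fell in them (camera adjusted p = 1.6e-17, and adjusted p = 0.16 with an estimated correlation). By edgeR 103 genes were higher and 89 lower in monocytes. The total was 545 with the fraction rule alone, 111 in DESeq2, and 125 without vehicle mouse 1.

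**Figure D3:**
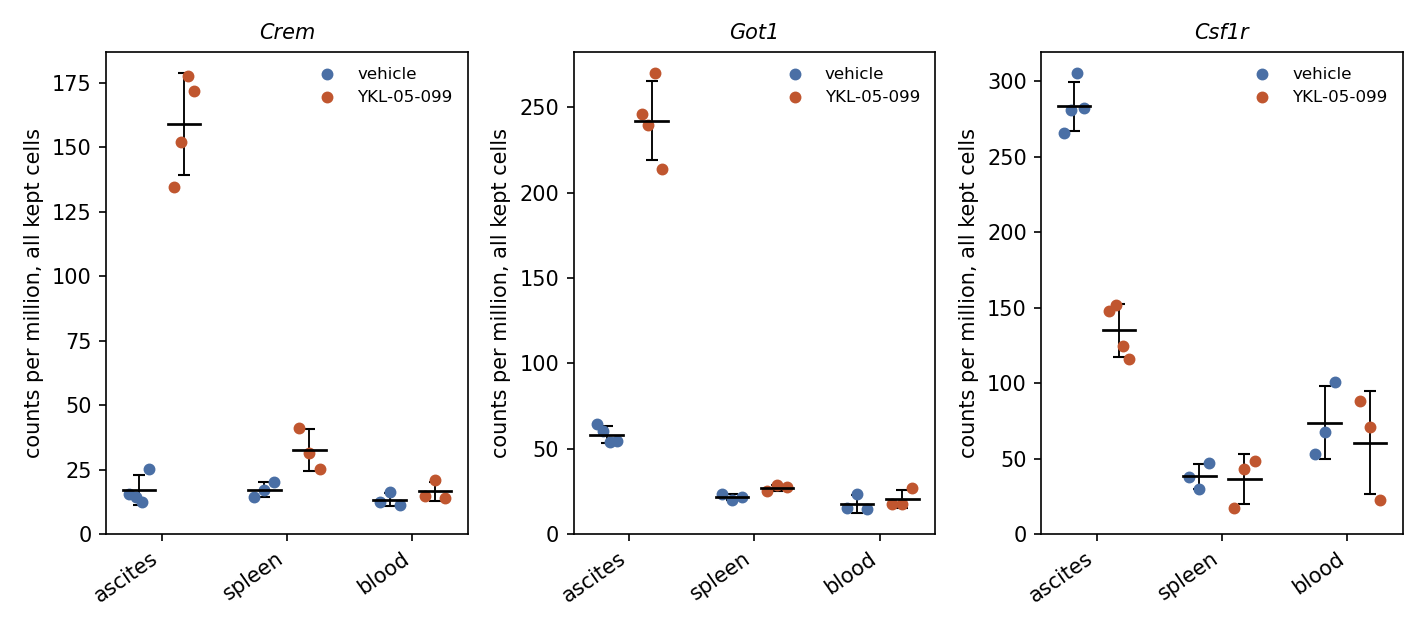
CPM over all kept cells of a mouse (y axis) for Crem, Got1 and Csf1r in ascites, spleen and blood; points are mice and bars give the mean ± SD, with 4 mice per arm in ascites and 3 in spleen and blood. In ascites Crem lies at 159 ± 19.7 in treated and 17.01 ± 5.76 in vehicle mice.

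T cells are the subject of the series title, and only 2 mice per arm (mice 1 and 4 of each) had the 20 cells per class that the tests required in ascites. In CD4 T cells Ramp3 rose by 5.62 ± 0.75, Myb by 3.15 ± 0.52, and Tnfrsf18, the costimulatory receptor GITR, by 1.90 ± 0.31 (n = 2 each, edgeR adjusted p = 1.6e-07, 3.4e-05 and 2.4e-05). Fosl2 (1.44 ± 0.28), Gimap3 (0.93 ± 0.21), Vps37b (0.81 ± 0.16) and Actg1 (0.75 ± 0.16) rose too. Tcf7, the transcription factor of naive and memory T cells and 1 of the 10 leading genes of the CD4 cluster, fell by 0.97 ± 0.20 (edgeR adjusted p = 0.0018), from 904.6 ± 109 to 514.4 ± 132 CPM. Txnip, Zfp36l2 and Junb were the others that fell (-0.86 ± 0.16, -0.83 ± 0.16 and -0.62 ± 0.14). Crem was at 1.89 ± 0.45 (edgeR adjusted p = 0.076), and Sik1, Sik3 and Nr4a1 did not pass the threshold.

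These 11 genes, 7 higher and 4 lower of 3725, were all that passed in CD4 T cells. The count was 0 in DESeq2. A simulation at this size, drawn from the dispersion trend of edgeR, recovered 54.1% of 4-fold changes in DESeq2 and 95.3% in edgeR. DESeq2 called 0 unchanged genes in it and edgeR 5. Changes as large as that of Ramp3 were not simulated, so it does not account for their loss. The count in edgeR was 5 without the low-count filter, 45 with at least 10 cells per mouse, 55 with the fraction rule alone, and 49 with both. Without vehicle mouse 4 it was 39, and without treated mouse 1 or treated mouse 4 it was 5 and 2, of which 4 and 0 were among the 11.

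In ascites CD8 T cells 0 of 3418 genes passed in edgeR (n = 2 each), with 123 at an unadjusted p under 0.05, and 0 passed in DESeq2. The smallest p values belonged to Crem (2.37 ± 0.53), the glycoprotein chaperone Mlec (2.32 ± 0.53), a pseudogene, Zfp36l2 (-0.98 ± 0.24) and Lyst (1.35 ± 0.34), with edgeR adjusted p of 0.576 to 0.665. Tcf7 was at -0.92 ± 0.30, Gzmb at 0.14 ± 1.80 and Ifng at -0.08 ± 1.53. At least 10 cells per mouse and the transcript gate gave 1 gene each, the fraction rule alone 3, and the fraction rule with at least 10 cells 7. Leaving out vehicle mouse 1, treated mouse 1 or treated mouse 4 gave 1, 24 and 29 genes.

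The third question was how the spleen and the blood of the treated animals differed from those of vehicle animals. Treated spleens held more B cells and fewer CD8 T cells, plasma cells, erythroid cells and macrophages. B cells were 26.2% ± 0.391 of vehicle and 43.0% ± 7.83 of treated spleen cells, and CD8 T cells 18.8% ± 1.77 and 12% ± 2.18 (n = 3 each). Plasma cells, the antibody-secreting descendants of B cells, were 4.43% ± 0.273 and 1.29% ± 0.384. Erythroid cells were 3.39% ± 1.16 and 1.06% ± 0.455, and macrophages, which in spleen express Vcam1 and C1qa, 2.50% ± 0.999 and 0.472% ± 0.552. The erythroid transcript Hbb-bs, summed over all kept spleen cells, was 2766 ± 1473 and 2424 ± 1323 CPM and overlapped (exact permutation p = 0.8). cDC1 were 2.0% ± 0.475 and 0.956% ± 0.388. The arms did not overlap in any of these 6 classes, or in pDC (0.858% ± 0.334 and 0.166% ± 0.169) and cDC2 (0.971% ± 0.133 and 1.38% ± 0.407), whose difference was -0.267 percentage points with the fraction rule alone. The exact two-sided permutation p of each was 0.1, the smallest that 3 against 3 mice allow, so no share of spleen or blood could pass 0.05. NK cells were 2.62% ± 1.05 and 5.32% ± 2.04, Treg cells 7.26% ± 1.85 and 6.22% ± 1.32, and non-classical monocytes 1.03% ± 0.420 and 2.26% ± 1.27, and these overlapped. All spleens together held 48 macrophages and 16 pDC, so the shares of these classes rest on few cells.

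In blood CD8 T cells were 14.4% ± 1.43 of vehicle and 9.28% ± 0.419 of treated cells, without overlap (exact permutation p = 0.1, n = 3 each). B cells (45.0% ± 3.1 and 50.1% ± 6.26), NK cells (9.76% ± 0.933 and 12.5% ± 3.87) and non-classical monocytes (3.89% ± 0.651 and 2.84% ± 1.64) overlapped. T cells as a whole fell in both tissues, from 33.6% ± 2.78 to 25.9% ± 1.68 in spleen and from 19.1% ± 2.71 to 12.6% ± 1.59 in blood (exact permutation p = 0.1 for each, n = 3 each).

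**Figure D4:**
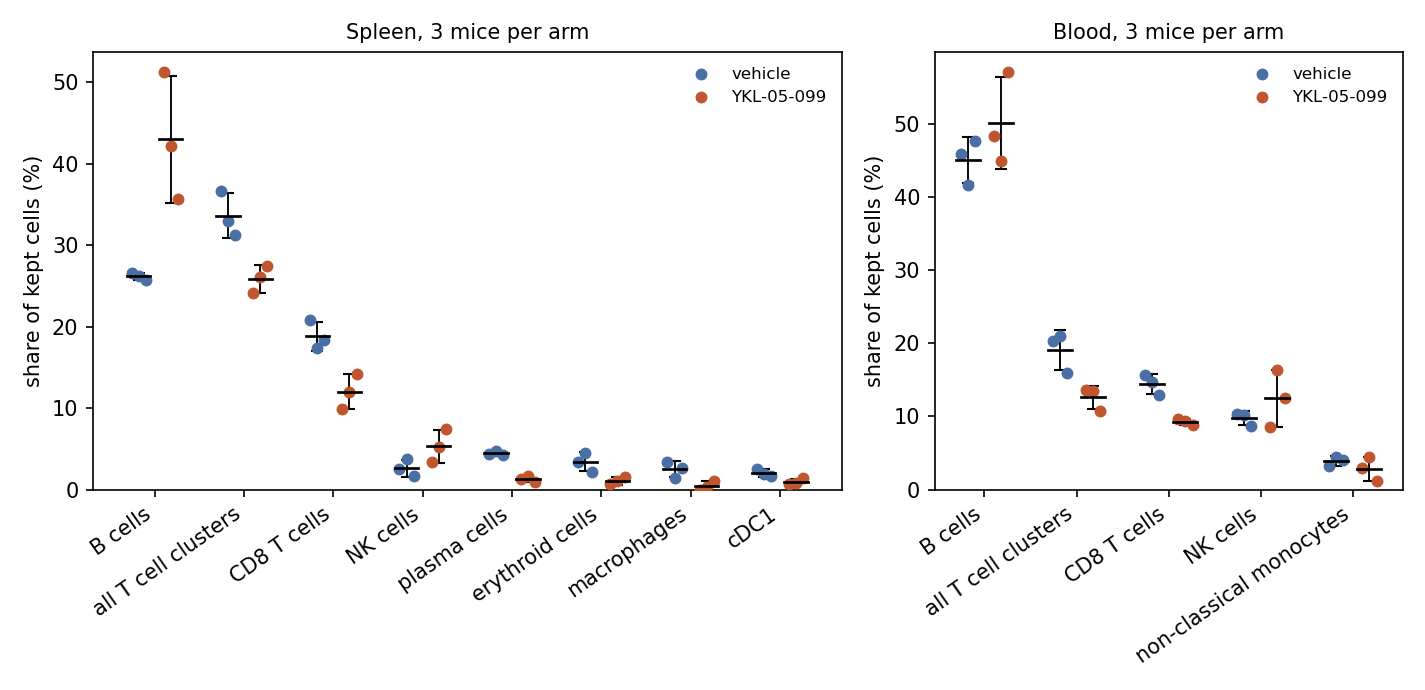
Share of kept cells (%, y axis) in spleen (left) and blood (right) for vehicle and YKL-05-099 mice; points are mice and bars give the mean ± SD of 3 mice per arm. Spleen B cells lie at 35.6% to 51.2% in treated and at 25.8% to 26.5% in vehicle mice.

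In spleen CD8 T cells of treated mice most of the genes that passed were lower, and many of them encode ribosomal proteins. Of 81 ribosomal protein genes 53 were lower and 0 higher, with a median log2 change of -0.20. Rbm3 and Cirbp, the cold-inducible RNA-binding proteins, fell by 0.90 ± 0.09 and 0.89 ± 0.21 (n = 3 each, edgeR adjusted p = 3.1e-09 and 0.0062). Igfbp4 (-1.60 ± 0.23), a transcript of naive T cells, and the survival gene Bcl2 (-0.67 ± 0.11) fell as well. Ifi27l2a rose by 1.15 ± 0.12 (edgeR adjusted p = 3.1e-09), from 200 ± 30.4 to 472 ± 30.9 CPM, with Bst2 (0.68 ± 0.17) and Samd9l (0.67 ± 0.16). The Hsp90 cochaperones Stip1 (1.02 ± 0.21), Cacybp (0.94 ± 0.18) and Chordc1 (0.68 ± 0.19) rose with Hsph1 (1.0 ± 0.21). In all 18 of 5407 genes were higher and 88 lower. Of 15 heat shock and unfolded protein genes 3 rose (camera adjusted p = 6.8e-11, and adjusted p = 0.204 with an estimated correlation). Of 9 type I interferon genes 2 rose (camera adjusted p = 2.4e-08, and adjusted p = 0.0865 with an estimated correlation). Adjusted over the list alone, 10 and 6 members rose. The haemoglobin transcript Hba-a2, a marker of erythroid cells, was also lower in these CD8 T cells (-1.48 ± 0.28), but was at 0.997 by a transcript gate (edgeR adjusted p = 0.944) and at -1.36 with at most 5% mitochondrial UMIs (edgeR adjusted p = 0.195). Tcf7 (-0.22 ± 0.12), Gzmb (0.37 ± 0.49), Ifng (0.15 ± 0.62) and Nr4a1 (-0.72 ± 0.24) were not past the threshold (edgeR adjusted p of 0.165 to 0.969). The count was 8, of which 6 were lower, when CD8 T cells were taken by a transcript gate, so most of the ribosomal falls were not called there. It was 36 with at most 5% mitochondrial UMIs and 63 without vehicle mouse 2. The class joins 2 clusters whose mix differed, with 178 of 290 vehicle and 108 of 225 treated cells in cluster 2. Fitted alone, as added after the data were seen, cluster 2 gave 45 genes and cluster 6 gave 7. Rbm3 (-1.07 and -0.81), Bcl2 (-0.84 and -0.65) and Cacybp (0.80 and 1.22) passed in both, Ifi27l2a (1.14) and Hsph1 (1.06) in cluster 2 only, and Cirbp, Stip1, Chordc1, Bst2 and Samd9l in neither.

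Spleen B cells had the largest count outside ascites, with 182 genes higher and 159 lower of 7498 by edgeR (n = 3 each). Ifi27l2a (1.44 ± 0.09), Ifi209 (1.06 ± 0.11) and Pde3b, a phosphodiesterase that breaks down cAMP (1.47 ± 0.14), rose. Fkbp5 (-1.72 ± 0.15), Fosb (-1.0 ± 0.08) and Rbm3 (-0.79 ± 0.07) fell. Of 11 type I interferon genes 6 rose and 0 fell, and of 16 heat shock genes 8 rose and 1 fell (camera adjusted p = 1.2e-11 for each, and adjusted p = 0.17 for each with an estimated correlation). Of 13 immediate early genes 7 fell and 1 rose (camera adjusted p = 5.1e-10, and adjusted p = 0.17 with an estimated correlation). Of 4 erythroid transcripts 3 fell (camera adjusted p = 3.5e-07, and adjusted p = 0.203 with an estimated correlation). Ribosomal protein genes went the opposite way to spleen CD8 T cells, with 22 of 81 higher and 0 lower. In ascites the direction varied by class, with 39 of 81 lower and 0 higher in B cells. There cDC1 had 30 lower and 1 higher, and macrophages 26 higher and 0 lower. In DESeq2 188 genes passed, and without vehicle mouse 2 the count was 193. Fitted apart, clusters 0, 1 and 3 of these B cells gave 85, 192 and 82.

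In the other spleen classes fewer genes passed. A T cell cluster marked by Cxcr6 (cluster 11 of this library) had 24 genes higher and 78 lower of 2057, of which 58 were ribosomal protein genes. The inducible chaperones Hspa1a (0.80 ± 0.11) and Hspa1b (0.73 ± 0.09) rose there and Bcl2 fell by 1.29 ± 0.18. In Treg cells Crip1 (1.22 ± 0.17) rose, and Ramp1 (-1.96 ± 0.36) fell, among 7 genes higher and 2 lower of 2846. Treg counts were 22 without the low-count filter, 17 in DESeq2, 23 without treated mouse 2 and 15 without vehicle mouse 3. The B cells marked by Bhlhe41 (2 vehicle and 3 treated mice) had 18 genes higher and 22 lower, with Id3 at -2.21 ± 0.31. Leaving out treated mouse 3, treated mouse 4 or vehicle mouse 1 gave 5, 85 and 21 genes, and at least 10 cells per mouse and DESeq2 gave 19 and 23.

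In blood fewer genes passed than in spleen for both B cells and CD8 T cells. B cells had 38 genes higher and 25 lower of 6352 by edgeR (n = 3 each), with Hspa8 at 0.72 ± 0.07, Plac8 at 0.54 ± 0.07 and Lmo2 at -0.95 ± 0.12. With at most 5% mitochondrial UMIs 5 passed, and without treated mouse 3 the count was 33. NK cells had 9 higher and 4 lower of 2283, with Ifngr1, the interferon gamma receptor (0.92 ± 0.14), Irf8 (0.82 ± 0.17) and Hspa8 (0.76 ± 0.14) higher and the chemokine Ccl3 (-1.37 ± 0.24) lower. DESeq2 called 1 gene in NK cells, and leaving out vehicle mouse 3, treated mouse 2 or treated mouse 3 gave 8, 8 and 6. In blood CD8 T cells Klrk1, the activating receptor NKG2D, was the only gene of 2657 that passed (2.15 ± 0.37, edgeR adjusted p = 2.1e-05, n = 3 each). DESeq2 called 0 genes there (195 had an unadjusted p under 0.05 in edgeR). Klrk1 was at 1.17 without treated mouse 3 (edgeR adjusted p = 0.847) and at 1.48 with the fraction rule alone (edgeR adjusted p = 0.749), and was not called by transcript gate or without the top Scrublet scores. Fits without 1 mouse gave from 2 genes (vehicle mouse 2) to 7 (treated mouse 4).

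The last question was whether the response of T cells differed between tissues. In a fit over spleen and blood CD8 T cells with the mouse as a block, 12 of 4716 genes differed in their response by edgeR. The block takes equal mouse numbers to be the same animal in both tissues. Ifi27l2a rose by 1.15 in spleen and was at 0.38 in blood, a difference of -0.78 ± 0.18 (edgeR adjusted p = 0.0115, 3 mice per arm). S100a10 and Lgals1 also had the higher response in spleen (differences of -0.75 ± 0.16 and -0.79 ± 0.20). Bcl2, Rbm3, Zfp36l2 and Tsc22d3 had the lower response in spleen (0.78 ± 0.18, 0.67 ± 0.16, 0.73 ± 0.16 and 0.80 ± 0.17), as was the haemoglobin transcript Hbb-bs (1.62 ± 0.33). Without the mouse block 3 genes passed, S100a10, Tsc22d3 and Rif1 (edgeR adjusted p = 0.0471 for each). Ifi27l2a, Zfp36l2 and Rbm3 (edgeR adjusted p = 0.0508 for each) and Bcl2 (0.246) did not. Leaving out treated mouse 2 or treated mouse 4 gave 1 and 6 genes, and leaving out vehicle mouse 1, vehicle mouse 2 or vehicle mouse 3 gave 3, 3 and 5. Between ascites and spleen CD8 T cells 0 genes differed in edgeR without a block, with 335 of 6038 at an unadjusted p under 0.05. The fit with the block left no residual degrees of freedom.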

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

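Of the tests in this part, only the difference in gene response between spleen and blood CD8 T cells and the comparison of macrophage genes with the RNA of T cells were set before their results were seen, and all others, the splits of the mice included, were chosen after. Outlying mice were looked for in 232 groups, of which chance picks out about 1 in 20.

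The first pattern is the smaller macrophage share of treated ascites. The assignment of hashtags may account for part of it, since the fraction rule, which keeps more cells with many UMIs, gave -6.86 percentage points with overlapping arms. Of the cells that either hashtag rule assigned, the main rule kept 196 of 584 in cluster 1 and 183 of 453 in cluster 5. It kept 237 of 527 in cluster 3, 81 of 109 in cluster 15 and 912 of 1084 in the larger B cell cluster. Shares of kept cells thus understate the macrophage clusters against B cells, cluster 1 the most. A loss of cells that need the CSF1 receptor is a biological alternative, and non-classical monocytes, which also need it, moved by -1.05 percentage points in blood and 1.23 in spleen, each with overlap. Neither explanation is excluded. Vehicle mouse 3 stood apart from its arm with 28.0%.

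The second pattern is the expression change of ascites macrophages. Classical monocytes that keep their Ly6c2 level, counted as macrophages, are unlikely to bring most of the rises. Of the other genes called higher, 99.8% need a larger monocyte share than Ly6c2 allows. That share is uncertain, since Chil3 gave a lower one and Vcan a higher one. Monocyte-derived cells that hold less Ly6c2 are not covered by this test, so they stay open. The test replaced an earlier version on Fn1 and F13a1, which vehicle macrophages express above monocytes. For free RNA of other cells, 20.6% of the genes called higher rose by more UMIs per macrophage than a T cell of the same mice holds. Allowing for the lower UMI count of treated macrophages, added after that value was seen, the share was 63.5%. A T cell also holds transcripts of its own, so a rise below its level does not mark a gene as free RNA. Both arms were pooled in the same library and share its free RNA, so the T cell level is no measure of a difference between them. The comparison thus cannot decide how far free RNA contributes, and this stays open.

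The third pattern is the rise of chaperone transcripts in treated cells. More handling stress in treated samples would likely raise immediate early genes too, but in spleen B cells 6 more of these were called lower than higher. That result was known when the comparison was chosen, so it cannot weigh against handling stress. Median mitochondrial UMIs were higher in every treated mouse of spleen (5.59% to 5.80% against 4.95% to 5.22%). The same held in blood (5.54% to 5.61% against 5.18% to 5.31%). A difference in cell quality is thus not excluded by this 1 class. A response to the drug stays open as a hypothesis, found on the same data.

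Splits of the mice into other groups of the same sizes were compared with the real one. In ascites only 1 of 35 splits, the real one, gave as many genes. The counts were 446 in B cells against at most 1 in another split, and 874 against 0 in cDC1. They were 192 against 49 in monocytes and 1235 against 2 in macrophages. A rank of 1 in 35 is the best these mice allow, and it was not corrected over the classes. Chance is thus unlikely there but not excluded. Spleen and blood allow 10 splits, too few for a share under 0.05. The real and highest other values were 341 and 0 for spleen B cells, 106 and 3 for CD8 T cells, 102 and 0 for cluster 11 and 9 and 3 for Treg cells. In blood they were 63 and 1 for B cells, 13 and 1 for NK cells, and 1 and 6 for CD8 T cells, where 4 splits gave as many. For the difference between spleen and blood CD8 T cells they were 12 and 4.

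Single mice stood apart in the T cell shares of ascites. Treated mouse 4 had 42.7% T cells, 24% CD4 T cells and 14.4% CD8 T cells, and vehicle mouse 4 had 11.6% CD4 T cells. In macrophages vehicle mouse 4 stood apart for Hspa8 (1798 CPM), Maf (321.8), Myc (82.41) and Plac8 (29.43), vehicle mouse 2 for Pltp (619.3) and vehicle mouse 1 for Vsig4 (419.3). Treated mouse 3 did for Ndufa2 (350 CPM) and treated mouse 4 for Vsig4 (18.01). Others were Ccr2 (170.8, vehicle mouse 1) and Fgl2 (192.8, treated mouse 3) in cDC1, Ffar2 (175.7, vehicle mouse 2) in cDC2 and Vps37b (113.9, vehicle mouse 2) in B cells.

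Between tissues, 12 genes differed in their response between spleen and blood CD8 T cells, whose mix of clusters also differed between the arms. Taking equal mouse numbers as the same animal, the B cell share of spleen minus that of ascites was 2.66 ± 2.32 percentage points in vehicle mice and 26.6 ± 11.6 in treated mice (exact permutation p = 0.1, the smallest possible, n = 3 each).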

How the results depend on the processing

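Alternatives named in the methods as added after seeing the data were chosen only then. Of the shares, 424 comparisons with an alternative kept direction and side of the threshold, 7 changed direction, 9 gained the threshold and 5 lost it. Of the gene counts 154 stayed within 1.5 times and 83 did not, and of the list counts 82 did and 40 did not. Named genes kept direction and side in 2971 comparisons, lost the threshold in 328, gained it in 27 and changed direction in 36. Some settings left too few mice for a class and gave no value, among them 5% mitochondrial UMIs, 50 cells per mouse and the transcript gate outside T cells, and 92 values of named genes could not be computed. Keeping Scrublet doublets changed nothing. The cause of the changes below was not tested.

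edgeR on cell counts gave log2 ratios past the threshold for ascites NK cells (-1.61), cluster 3 (-2.23), cluster 11 (1.92) and migratory dendritic cells (1.57), and for spleen plasma cells (-1.77), erythroid cells (-1.65), macrophages (-2.34) and pDC (-2.25). It also did for cluster 15 (-7.04), with 0 cells in treated mice, so that this value is no measure of its size. The spleen ratios of macrophages and pDC rest on few cells. Vehicle mice 1, 2 and 3 had 19, 7 and 13 macrophages and 3, 4 and 6 pDC. Treated mice 2, 3 and 4 had 0, 2 and 7 macrophages and 1, 2 and 0 pDC. As a share of lymphocytes all T cells of ascites differed by 29.1. The share of all macrophage clusters lost the threshold with the fraction rule alone (-6.86) and without unnamed clusters (-8.17), where the arms overlapped. Leaving out single mice gave -8.74 to -4.97 without overlap. Without both mice 4 the difference was -7.06, also without overlap, and 3 against 3 mice allow no p under 0.1. Leaving out single mice gave -1.11 to 5.96 for ascites CD4 T cells, -0.227 to 3.41 for CD8 T cells, -0.104 to 2.05 for classical monocytes and -2.27 to 0.224 for cDC2. With at most 5% mitochondrial UMIs ascites CD8 T cells were at -0.0685 and spleen Treg cells at 2.28. With the fraction rule alone spleen cDC2 were at -0.267.

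Gene counts under DESeq2 were 284 (ascites B cells), 0 (CD4), 575 (cDC1), 123 (cDC2), 111 (monocytes), 188 (spleen B cells), 23 (cluster 7), 17 (Treg), 0 (blood CD8) and 1 (NK). With 5% mitochondrial UMIs they were 27 (ascites B cells), 657 (macrophages), 36 (spleen CD8) and 5 (blood B cells). The fraction rule alone gave 55 (CD4), 3 (CD8), 745 (cDC2), 545 (monocytes) and 2383 (macrophages), and with at least 10 cells 49 (CD4) and 7 (CD8). At least 10 cells alone gave 45 (CD4), 1 (ascites CD8) and 19 (cluster 7), and at least 50 gave 745 (macrophages). Without the low-count filter there were 5 (CD4), 22 (Treg) and 3 (blood CD8), by transcript gate 1 (ascites CD8) and 8 (spleen CD8), and without the top Scrublet scores 17 (CD4) and 0 (blood CD8). Single clusters gave 296 (ascites B cells, cluster 0), 85, 192 and 82 (spleen B cells, clusters 0, 1 and 3), 45 and 7 (spleen CD8, clusters 2 and 6), 4 (blood B cells, cluster 3) and 0 (blood CD8, cluster 2). Within classes, mice of equal number in the 2 arms did not deviate together (correlations near 0), so the numbers were not taken as pairs. Over all kept ascites cells the correlation was 0.335 for mice 4, and 0.073, -0.048 and 0.026 for mice 1, 2 and 3. A replicate block gave 8 (ascites CD8), 412 (cDC2), 66 (spleen B cells), 54 (spleen CD8), 45 (spleen cluster 11), 25 (Treg), 11 (blood B cells), 38 (blood CD8) and 1 (NK).

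Leaving out single mice gave 296 to 477 genes (ascites B cells), 2 to 39 (CD4), 0 to 29 (CD8), 99 to 380 (cDC2), 125 to 238 (monocytes), 193 to 314 (spleen B cells), 63 to 127 (spleen CD8), 5 to 85 (cluster 7), 7 to 23 (Treg), 33 to 57 (blood B cells), 2 to 7 (blood CD8) and 6 to 13 (NK). An arm left with 1 mouse is assumed to vary like the other. The difference between spleen and blood CD8 T cells was 1 to 8 genes without single mice and 3 without the mouse block.

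With an estimated correlation 0 lists passed in each of the 15 classes. fry gave 4 lists (ascites B cells), 0 (ascites CD8), 2 (cDC2), 1 (monocytes), 4 (spleen B cells), 1 (spleen CD8), 0 (cluster 7), 0 (Treg), 2 (blood B cells), 1 (blood CD8) and 0 (NK). Leaving out single mice gave 0 to 4 lists (ascites CD4), 3 to 10 (CD8), 6 to 11 (cDC2), 4 to 7 (spleen CD8), 2 to 6 (spleen cluster 11), 3 to 8 (cluster 7), 3 to 9 (blood B cells), 1 to 6 (blood CD8) and 3 to 5 (NK).

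Of named genes, 2 that were called changed direction, Hba-a2 in spleen CD8 T cells (0.997 by transcript gate) and Zfp36 in macrophages (0.20 with 5% mitochondrial UMIs). The others were not past the threshold. In ascites CD8 T cells Ifng was 0.092 by transcript gate, 0.026 with at least 10 cells, 0.34 in DESeq2 and -3.3 to 1.3 without single mice. Gzmb was -0.060 with the fraction rule alone, -0.89 without the top Scrublet scores, -0.16 with a replicate block and -3.3 to 1.52 without single mice. Sik1 in CD4 T cells ranged from -1.0 to 0.47 without single mice. In macrophages Nr4a1 was 0.18 with 5% mitochondrial UMIs, 0.11 with the fraction rule alone, 0.018 with a block, 0.080 without both mice 4 and -0.22 to 0.16 without single mice. In spleen CD8 T cells Sik3 was -0.17 by transcript gate. Sik3 was -0.033 without the top Scrublet scores and -0.21 to 0.36 without single mice. Sik2 was -0.020 with the fraction rule alone, -0.0016 with a block and -0.14 to 0.56 without single mice. Ifng was -0.35 in cluster 6 alone and -0.42 to 1.27 without single mice, and Gzmb -0.10 with the fraction rule alone and -0.28 with a block. In blood CD8 T cells Tcf7 was -0.032 without the low-count filter and -0.051 to 0.17 without single mice.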

Other observations

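The counts and tests in this part were chosen after the data were seen. Mast cell transcripts, 7 summed, reached at least 50 UMIs in 5 of 1895 kept cells of treated ascites, in 3 mice, and in 0 of 2473 of vehicle ascites, where 3 cells would be 0.121%. These cells held 1428 to 3123 such UMIs, and 4 of them lay in cluster 11. With the fraction rule alone there were 7 of 2847 cells in 4 treated mice and 0 of 3572 in vehicle mice. The difference was not tested.

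Over all kept cells of a mouse, Ramp3 went from 11.4 ± 3.03 to 128 ± 22.96 CPM in ascites (exact permutation p = 0.0286, n = 4 each), and was 2.32 ± 0.991 and 1.85 ± 0.541 in spleen (exact permutation p = 0.4, n = 3 each). C1qa, C1qb and C1qc together were 125.6 ± 53.1 CPM in vehicle and 12.7 ± 13.8 in treated spleen (exact permutation p = 0.1, the smallest possible, n = 3 each).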
